A study of Mus musculus with 2 samples.

How the data were processed

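Brains of 5 mice per condition were dissociated to single cells, freed of myelin on a density gradient, pooled by condition and run on the 10x Genomics 3′ platform (v3.1 chemistry), per the labels' protocols. The deposited matrices hold raw UMI counts per gene and cell barcode that the authors made with Cell Ranger 7.0.1 on mm10, and Seurat 4.3.0 is also named, per the submitters' processing notes. Which barcodes the authors kept for their own figures, and their cell type names, are not given in the sources used here. The counts were used as deposited, for 32285 genes in both libraries. The lowest barcode total was 500 UMIs in each library.

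The group of each library was taken from its treatment field. The title of each library names the opposite surgery, and nothing in the labels settles which is right, so all differences are written as treatment-MI library against treatment-sham library. Each group is 1 library of pooled mice. Cells are not replicates, so no test, p-value or standard error was computed.

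Barcodes with under 300 detected genes or over 10% mitochondrial UMIs were left out (1857 and 353 barcodes). Scrublet was run per library, and the barcodes with the highest scores were left out as doublets at a rate of 0.8% per 1000 barcodes, which was 969 barcodes (8.81%) and 487 barcodes (6.24%). Scrublet's automatic threshold would have called 328 and 170. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells were clustered over both libraries together by the Leiden method at resolution 1 on 15 neighbours, with no integration (Python 3.11, scanpy 1.11.5, igraph, scikit-learn).

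Clusters were named from marker genes. These markers, the gene lists and the rule for named genes were fixed before the data were examined. A name needed at least 3 detected markers (20 CPM or more), at least 2 own markers among the top 50 genes and more than any other class there, and no more markers of another class than own ones among the top 10. Clusters whose median UMI count, times 3, was below that of their library needed an own marker among the top 10 genes. Top genes were ranked by fold against the cells of other classes, but for this last condition against all other cells. It left unnamed 1 cluster of 199 and 13 cells that was otherwise astrocyte-like. How these markers were scored, and the rule that clusters with any of 7 pituitary hormone genes among their top 10 genes keep no cell type name, were set after seeing the data. The latter took 619 cells of the treatment-MI library and 5 of the treatment-sham library out of named classes.

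Within a class, UMI counts were summed per library and scaled to a class sum of 1000000, giving CPM. A gene counted as measured with at least 50 UMIs over both libraries and 20 CPM in 1 or both. Log2 ratios carry the exact conditional binomial 95% interval of the pair of Poisson counts, shares the exact Clopper-Pearson interval, and CPM the exact Poisson interval. These cover counting error only, not differences between mice, cells or library preparations. A gene at 0 UMIs was set at the limit of 3 counts, and the limit given for a share of 0 cells is 3 cells of the total. For 23 gene lists, the median log2 ratio of the measured members (at least 4) was placed among 10000 random lists of the same size, matched on expression in 20 bins. This describes these libraries and is no test of the surgery.

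Single genes were named by 1 rule: measured genes other than mitochondrial, ribosomal protein, haemoglobin, unnamed-model and other classes' marker genes, whose CPM in the higher library, times 5, reached the highest CPM in any other class of that library, so that free RNA could not supply it, and whose sign held after median-ratio scaling. They were ranked by the interval bound nearest 0, with 10 taken in each direction. A level that free RNA could supply means below one that fell under this CPM limit. The limit is not a measured level of free RNA. From described lists, up to 4 of the members with the most UMIs were named, and Ccr2, Ccl2 and the free RNA genes Hbb-bs and Ttr always. Some genes that this rule takes are not reported here. Ccl3 and Icam1 in microglia-like cells, Cd9 in astrocyte-like cells, S100a8 and S100a9 in macrophages, Gh, the genes shared between classes, and the genes named for the number of cells behind them were chosen after their values were seen. For shares of cells with a UMI, each cell was thinned at random to 1000 UMIs and shallower cells were left out.

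On simulated microglia-like counts with 200 of 6865 genes changed, 94.9% of intervals held the true ratio, and a planted list of 10 genes at log2 0.5 came out at percentile 100. Of 200 lists of unchanged genes, 6 fell outside percentiles 2.5 to 97.5. The simulation draws Poisson counts and so does not cover genes whose UMIs come from few cells.

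Gene coordinates, transcript lengths and the share of 31-base words of the last 400 bases found in other genes' transcripts came from GENCODE M21 on GRCm38, the assembly that mm10 names, which held 32235 of the 32285 gene identifiers. The length of a gene was the median over its annotated transcripts of the gene's own type, or over all if none had that type. Lengths expressed in these cells were not measured, so the tests of length cover annotated length only. The release used by the authors is not given in the sources used here. Alternatives covered the cell filter, doublets, clustering, scaling, minimum counts, thinning and denominators, and the closing section gives their effect.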

Results

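Single-cell RNA was counted in the brains of adult female C57BL/6J mice collected 7 days after surgery, which was either a sham operation or an induced myocardial infarction (MI). Each condition was a pool of 5 brains that gave a single droplet library, so there was 1 library per group. The title and the treatment field of each library disagree: the library whose treatment field reads MI carries a title naming sham, and the library whose treatment field reads sham carries a title naming MI. The libraries are therefore called the treatment-MI library and the treatment-sham library, after the treatment field, and each difference is given as treatment-MI against treatment-sham. Which surgery a difference follows is not known from these labels. With no replicate library, no test between conditions was possible, and the 95% intervals below cover counting error only.

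The treatment-MI library held 11005 barcodes with 93142820 unique molecular identifiers (UMIs), and the treatment-sham library held 7804 barcodes with 37114825 UMIs, against a target of 10000 cells each. The median depth was 6531 UMIs and 2742 genes per barcode in the treatment-MI library and 4075.5 UMIs and 2041.5 genes in the treatment-sham library. After the cell filters, 8211 and 6970 cells were kept, with median depths of 6926 and 4059 UMIs, a ratio of 1.71.

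The first comparison asked which cell types the libraries held and in what shares. Microglia-like and astrocyte-like cells made up most of both. Microglia-like cells, the resident macrophages of the brain, were 44.6% of kept cells in the treatment-MI library (3666 cells, exact Clopper-Pearson interval 43.6% to 45.7%) and 49.6% in the treatment-sham library (3457 cells, 48.4% to 50.8%). Astrocyte-like cells were 34.1% (33.1% to 35.2%) and 41.0% (39.9% to 42.2%). T cell-like cells, which included an NK cell-like sub-cluster of 12 and 4 cells, were 1.02% (84 cells, 0.817% to 1.26%) and 0.617% (43 cells, 0.447% to 0.830%), a 1.66-fold higher share in the treatment-MI library (1.14 to 2.45). B cell-like cells were 0.280% (23 cells) and 0.1004% (7 cells), a ratio of 2.79 (1.16 to 7.70). Whether these T and B cells came from brain tissue or from blood, whose erythroid-like cells are given below, was not tested. Border-associated macrophage-like cells, which line the meninges and vessels, were 1.94% (1.65% to 2.26%) and 1.58% (1.30% to 1.90%), and the interval of this 1.23-fold ratio reached from 0.956 to 1.58. Oligodendrocyte-like cells, which make myelin, were 1.04% and 1.15%, a ratio of 0.902 (0.657 to 1.24). Neutrophil-like cells were 0.195% and 0.373%, a ratio of 0.522 (0.262 to 1.01).

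The widest differences in share lay outside these classes. Clusters led by genes of anterior pituitary hormones, among them Gh (growth hormone), Prl (prolactin) and Pomc (the precursor of adrenocorticotropic hormone), held 619 cells or 7.54% of the treatment-MI library (6.98% to 8.13%) and 5 cells or 0.0717% of the treatment-sham library (0.0233% to 0.167%). The 5 cells had 0 UMIs of Gh, Prl, Cga and Pomc and all had a UMI of a neuron gene, so they were grouped with these clusters without these hormone genes. The largest of these clusters had a median of 23879 UMIs per cell. Erythroid-like cells were 1.71% (140 cells) and 0.0717% (5 cells). A cluster of few UMIs per cell, led by astrocyte genes such as Aldoc and Cspg5 against cells of other classes but by Nrgn and the platelet genes Ppbp and Pf4 against all other cells, was left unnamed and was 2.42% and 0.187%. With these clusters left out of the denominator, a choice made after seeing the data, microglia-like cells were 50.5% (49.4% to 51.7%) and 49.8% (48.6% to 50.9%), so that their lower share in the treatment-MI library was not kept. The astrocyte-like shares were then 38.6% (37.5% to 39.8%) and 41.2% (40.0% to 42.3%). The unnamed cluster left out here held 199 and 13 cells and was otherwise astrocyte-like. Counting its cells as astrocyte-like would narrow this gap.

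**Figure D1:**
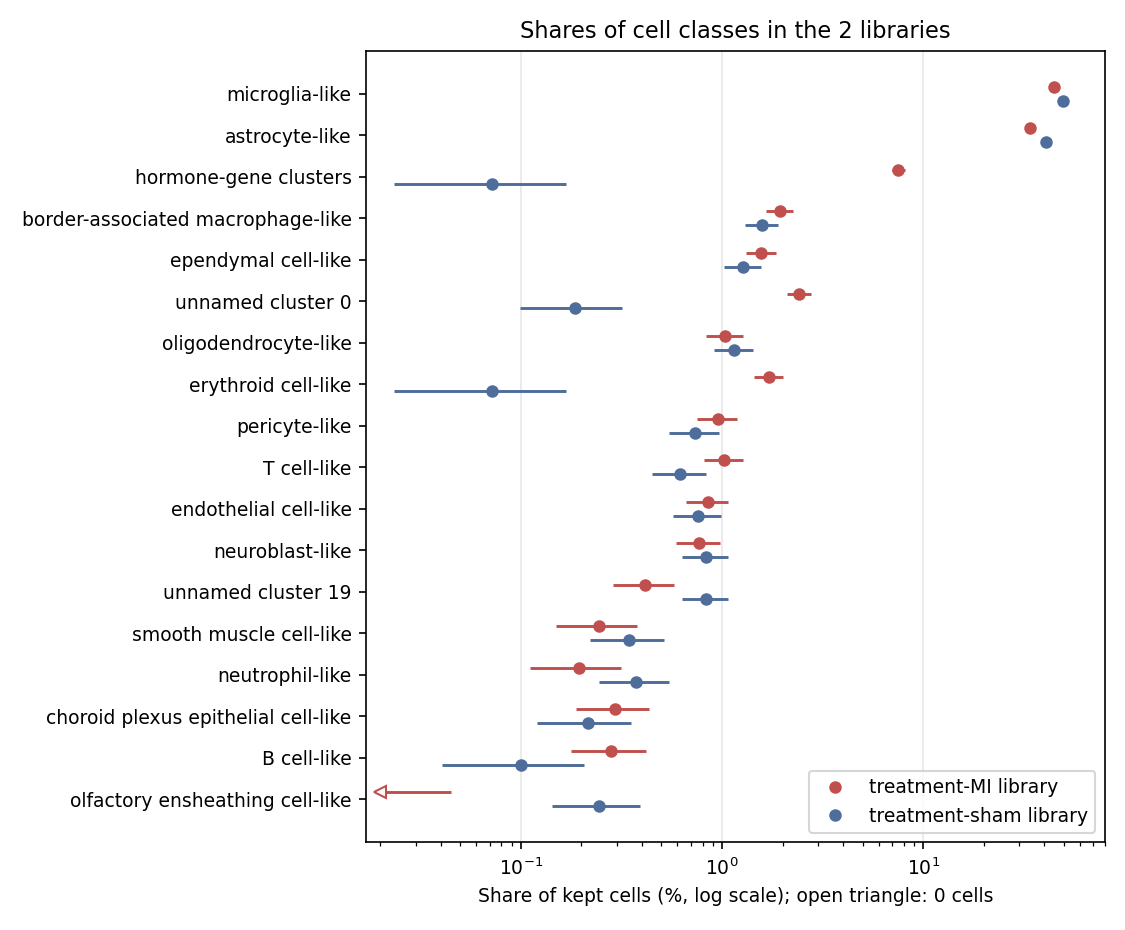
Share of kept cells (percent, log scale) in each cell class or unnamed cluster, as points with exact 95% Clopper-Pearson intervals for the treatment-MI library and the treatment-sham library; the intervals cover counting error only, and the open triangle marks 0 cells. The hormone-gene clusters stand at 7.54% against 0.0717%, while most named classes have overlapping intervals.

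Genes were then compared within each class that held at least 100 cells in each library, which were the microglia-like, astrocyte-like and border-associated macrophage-like classes. In microglia-like cells the MHC class I list, genes that present peptides to CD8 T cells, was higher in the treatment-MI library. Its median log2 ratio was 0.52, at percentile 99.99 among 10000 random lists matched on expression, with 6 of 9 measured members above 0. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083 in mm10), the shared light chain, was 2.23-fold higher (28620 UMIs against 7216, log2 interval 1.12 to 1.19). H2-D1 was 2.25-fold higher, but 39.8% of its 3′ end is shared with other genes, so that its count is uncertain. H2-K1 was 1.26-fold higher at a level that free RNA from other cells could supply, and Psmb8, a subunit of the immunoproteasome, was at log2 -0.10 (-0.17 to -0.03). The list of NF-kB targets and inflammatory cytokines had a median of 0.22 (percentile 99.95), with 10 of 12 members above 0, and the median was 0.61 without a minimum CPM and with 10 UMIs as the minimum. Among the members the chemokine genes Ccl4 and Ccl3 were 2.05-fold and 1.91-fold higher, Cd14, a receptor of bacterial lipopolysaccharide, was 1.60-fold higher, and Nfkb1 was at log2 0.17. Icam1 was at 0.801 of the treatment-sham level. Immediate early genes, which also respond to tissue dissociation, had a median of 0.12 (percentile 98.18) and heat shock genes one of 0.14 (percentile 97.88) in the same cells, so a difference in handling stays open here. The interferon list had a median of 0.23 (percentile 99.18) with all 6 measured members above 0, among them Bst2 at log2 0.45 and Slfn2 at 0.02 (-0.12 to 0.16), both of which free RNA could supply.

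Genes of the disease-associated microglia list, a state described in neurodegeneration, had a median of -0.22 in microglia-like cells (percentile 0.41), with 7 of 11 measured members below 0. Ctsd, a lysosomal protease, was at 0.752 of the treatment-sham level, Trem2, a lipid receptor, at 0.739 and Tyrobp, its adaptor, at 0.797, while Cd9 was 1.81-fold higher. Without a minimum CPM and with 10 UMIs as the minimum, the median was 0.23, so the direction of this list depended on the genes admitted. Apoe was 1.26-fold higher, but its level in microglia-like cells lay under the free RNA limit set by astrocytes. After thinning, 35.8% and 31.6% of microglia-like cells had an Apoe UMI. In T cell-like cells, which should lack the gene, the shares were 9.52% (4.20% to 17.9%) and 7.14% (1.50% to 19.5%). This argues against free RNA as the only source of Apoe in microglia-like cells, but its part in the ratio was not measured. Homeostatic microglia genes had a median of 0.019 (percentile 55.08), with P2ry12 at log2 0.19 and Cx3cr1 at -0.09. All 13 mitochondrially encoded genes were above 0 (median 0.39). Microglia-like cells were spread unlike over clusters in the libraries. Cluster 7 held 44.2% of them in the treatment-MI library and 2.57% in the treatment-sham library, and cluster 8 held 4.94% and 61.2%. Cluster 6 was large in both, at 41.3% and 26.4%. The clustering used no integration, and the libraries differed in depth and free RNA. These shares therefore do not tell a change of cell state from a difference between libraries. Cluster 14 of this class was led by immediate early genes such as Egr1 and Atf3, and cluster 15 by interferon genes such as Ifit2.

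By the rule fixed for single genes, the 10 highest in microglia-like cells of the treatment-MI library were Cebpb, Trerf1, Snhg8, Pfn1, Snrpf, Zfp36, Smim26, Alyref, Cox17 and Lsm5. Cebpb (ENSMUSG00000056501, chromosome 2, 167688915 to 167690418), a transcription factor of inflammatory genes, was 277 CPM against 58.5 CPM (log2 2.25, interval 2.14 to 2.35), and Pfn1, an actin-binding protein, was 512 CPM against 158 CPM (log2 1.70, 1.63 to 1.76). Zfp36, which speeds the decay of cytokine messenger RNA and is also a member of the immediate early list, had a log2 ratio of 1.41. The 10 lowest were Ppan, Mthfd2, Adamts16, Tln1, Mrpl28, Prxl2b, Comtd1, Haghl, Actb and Sf3b2, with log2 ratios from -0.76 to -0.47. Actb was 5624 CPM against 7797 CPM.

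In astrocyte-like cells the MHC class I list had 4 measured members and a median of 0.73 (percentile 99.91), which was 0.38 without a minimum CPM and with 10 UMIs as the minimum, and could not be measured in 5 other settings. The 4 were B2m at 2.25-fold, H2-D1 at 1.73-fold, Tap2 at 1.58-fold and H2-K1 at 0.975. Of these only Tap2, a peptide transporter, lay above the level that free RNA from other cells could supply. The 8 measured genes of the disease-associated microglia list had a median of -0.27 (percentile 0.060), which was -0.0557 without a minimum CPM and with 10 UMIs as the minimum. Among them Apoe, the main lipid carrier made by astrocytes, was 16932 CPM against 23009 CPM, a log2 ratio of -0.44, and Cd63 was at -0.32, while Cd9 was at 0.98. Glycolysis genes had a median of -0.12 (percentile 3.30), with 10 of 12 below 0, among them Gapdh at log2 -0.39 and Aldoc at -0.26. Glucocorticoid response genes had a median of 0.055 (percentile 84.7). Mitochondrially encoded genes had a median of 0.24, with 12 of 13 above 0.

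The 10 highest single genes in astrocyte-like cells were Bambi, Myoc, Krt10, Bloc1s1, Smim26, Cox17, Alyref, Ndufb1-ps, Tmem128 and Ost4. Bambi, a decoy receptor of TGF-beta signalling, was 35.8 CPM against 10.5 CPM (log2 1.77, 1.52 to 2.03), with UMIs in 572 of 2802 and 138 of 2859 cells. For Myoc 98.6% of the UMIs in the treatment-MI library came from 5 cells, so that its ratio describes few cells. The 10 lowest were Padi2, Gdf11, Lynx1, Tmem186, Btbd17, Apoe, Igf2bp3, Ccdc152, Arl6ip4 and Wscd1, with log2 ratios from -0.65 to -0.44.

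**Figure D2:**
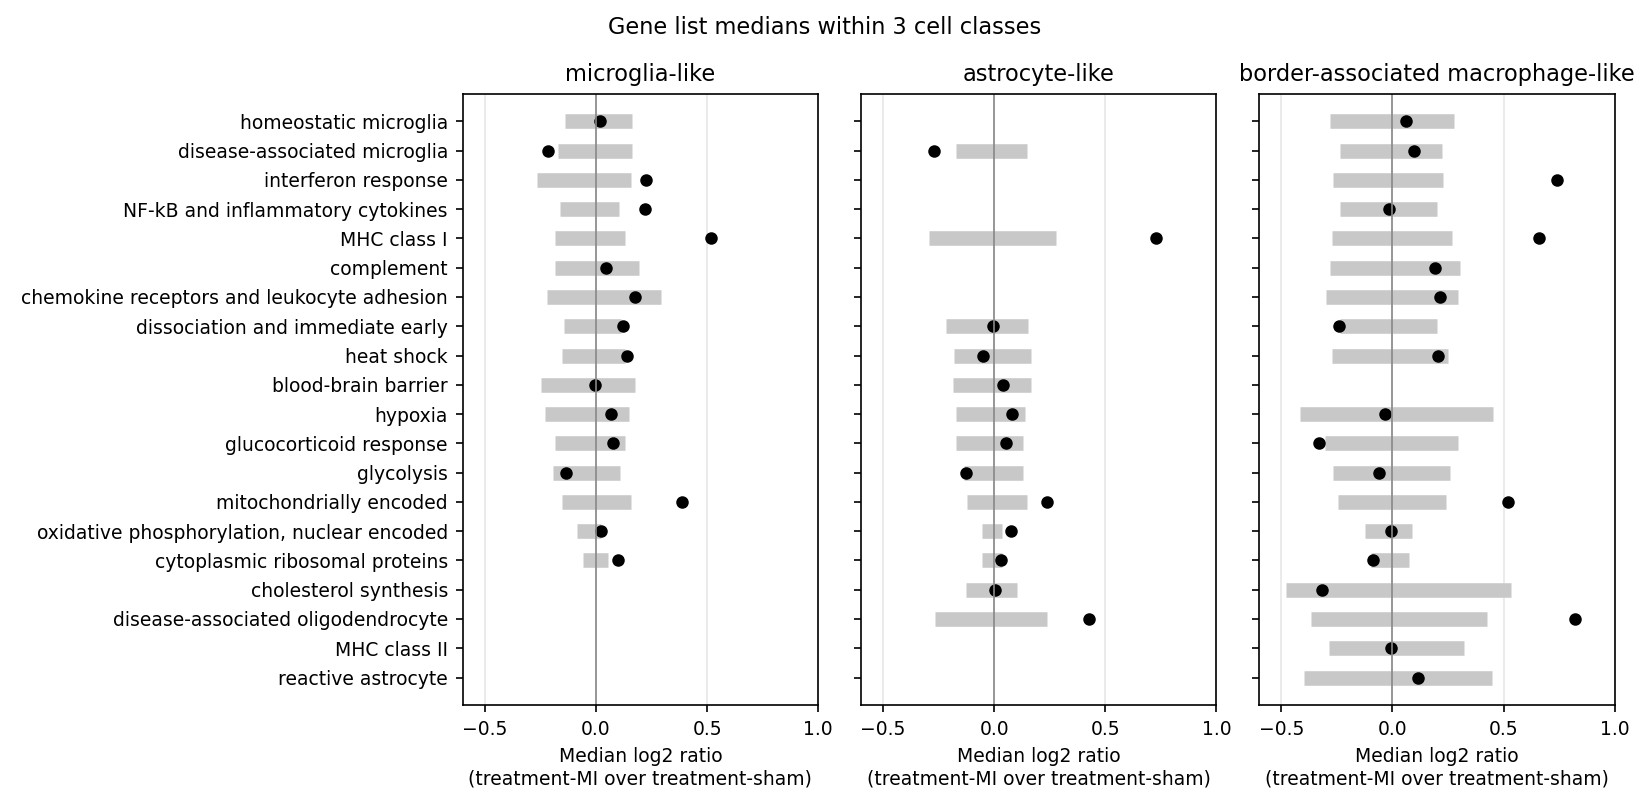
Median log2 ratio (treatment-MI over treatment-sham library) of each measured gene list in microglia-like, astrocyte-like and border-associated macrophage-like cells, as points, with grey bars for the middle 95% of medians of 10000 random lists matched on expression. MHC class I lies above the bars in the 3 classes at 0.52, 0.73 and 0.66, and the interferon list in border-associated macrophage-like cells lies at 0.74.

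The study's title concerns monocytes with the chemokine receptor CCR2, so Ccr2 and its ligand genes were read in the border-associated macrophage-like class, the class with the highest Ccr2 level among those examined. Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557 in mm10) was 233 CPM in the treatment-MI library (306 UMIs, exact Poisson interval 207 to 260) and 249 CPM in the treatment-sham library (133 UMIs, 209 to 295), a log2 ratio of -0.10 (-0.40 to 0.21). The border-associated sub-clusters of the class (130 and 87 cells) held 124 of the 306 and 49 of the 133 UMIs, and the others lay in the monocyte-like sub-cluster and an unnamed one of 20 and 15 cells whose leading genes include Cd209a and Mgl2. With each cell thinned to 1000 UMIs, 10 of 155 cells had a Ccr2 UMI (6.45%, 3.14% to 11.5%) against 10 of 107 (9.35%, 4.57% to 16.5%), with 4 and 3 shallower cells left out. Before thinning the shares were 32.7% and 37.3%. In astrocyte-like cells, which should lack the gene, 0 of 2797 and 0 of 2832 thinned cells had a Ccr2 UMI, which allows shares of up to 0.107% and 0.106%. The median depth was 7274 and 4351.5 UMIs in the macrophage class and 7850 and 4512 UMIs in the astrocyte-like class. In T cell-like cells 13 of 84 (15.5%, 8.51% to 25.01%) and 4 of 42 thinned cells (9.52%, 2.66% to 22.6%) had a Ccr2 UMI. In microglia-like cells the thinned share was lower in the treatment-MI library, at 4 of 3656 (0.109%, 0.0298% to 0.280%) against 13 of 3409 (0.381%, 0.203% to 0.651%), but the order was the opposite before thinning (1.23% against 0.955%). Ccr2 in the summed UMIs of microglia-like cells was 2.36 CPM (57 UMIs) and 2.65 CPM (36 UMIs). The interval of its log2 ratio of -0.17 held 0 (-0.79 to 0.48). Over all kept cells the thinned share with a Ccr2 UMI was 0.348% (0.232% to 0.503%) and 0.393% (0.259% to 0.571%), and 1.57% and 1.26% before thinning. A monocyte-like sub-cluster of the macrophage cluster, led by Plac8 and Chil3, held 9 cells (0.110% of kept cells, 0.0501% to 0.208%) and 8 cells (0.115%, 0.0496% to 0.226%). A difference in Ccr2 in the macrophage class, or in the share of monocyte-like cells, was not detectable at this depth.

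Ligand genes of this receptor were higher in the treatment-MI library in the same class. Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) was 820 CPM (772 to 871) against 109 CPM (82.5 to 140), a 7.55-fold higher level (log2 2.92, 2.54 to 3.32). Its neighbours on chromosome 11, Ccl7 and Ccl12, were 4.63-fold and 4.31-fold higher. After thinning, 31 of 155 cells had a Ccl2 UMI (20%, 14.0% to 27.2%) against 5 of 107 (4.67%, 1.53% to 10.6%), and 35.2% against 15.5% before thinning. In astrocyte-like cells 0 of 2797 and 0 of 2832 thinned cells had one. The UMIs were unevenly spread, since 5 cells held 46.4% of the Ccl2 UMIs in the treatment-MI library and 72.4% in the treatment-sham library. In microglia-like cells Ccl2 was 20.1 CPM against 11.3 CPM (log2 0.83, 0.57 to 1.11), under the free RNA limit of the rule for single genes. In astrocyte-like cells Ccl2 was only 0.458 CPM and 0 CPM. After thinning, 56 of 3656 and 28 of 3409 microglia-like cells had a Ccl2 UMI. These values argue against free RNA as the main source of Ccl2 in microglia-like cells. Il1b in the macrophage class was lower in the treatment-MI library, at 329 CPM (299 to 362) against 515 CPM (456 to 580), while the shares of cells with a UMI gave no order, at 13.5% (8.59% to 19.96%) and 16.8% (10.3% to 25.3%) after thinning and 31.4% and 26.4% before. In astrocyte-like cells 0 of 2797 and 1 of 2832 thinned cells had an Il1b UMI.

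**Figure D3:**
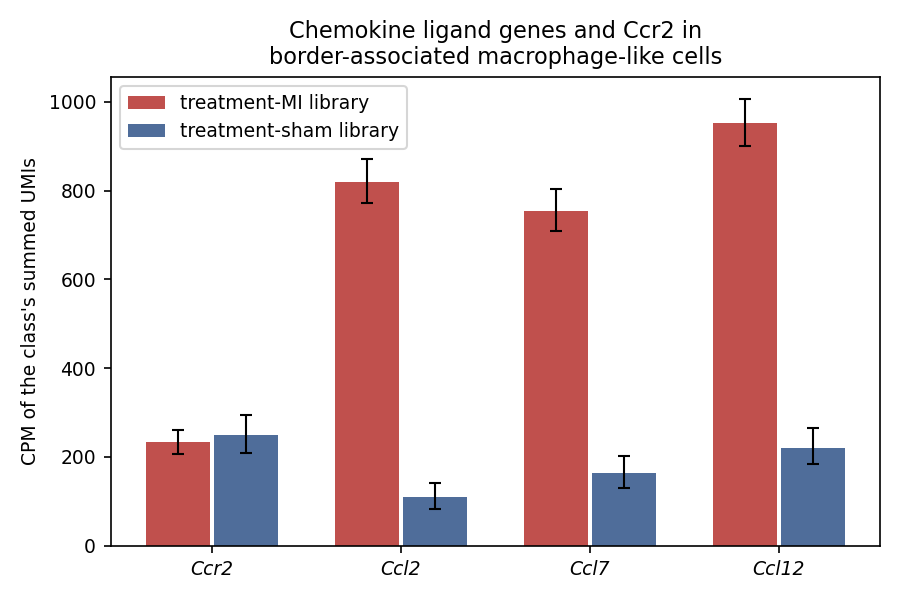
Level of Ccr2 and of the chemokine genes Ccl2, Ccl7 and Ccl12 in border-associated macrophage-like cells, in CPM of the summed UMIs of the class, for the treatment-MI library (159 cells) and the treatment-sham library (110 cells). Bars start at 0 and error bars are exact 95% Poisson intervals of the UMI counts; Ccl2 stands at 820 against 109 and Ccr2 at 233 against 249.

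The interferon list in border-associated macrophage-like cells had a median of 0.74 (percentile 100), with 13 of 16 members above 0. Ifi27l2a was 1.63-fold and Bst2 1.72-fold higher, while Ifitm3 was at 0.770 of the treatment-sham level and Slfn2 at log2 -0.11. MHC class I had a median of 0.66 (percentile 100), with 8 of 10 members above 0, among them B2m at 2.71-fold. MHC class II genes, which present antigen to CD4 T cells, had a median of -0.0044 (percentile 58.9) whose sign changed with median-ratio scaling, with Cd74 at log2 -0.03 and H2-Aa at 0.38. The NF-kB and cytokine list had 7 members above and 7 below 0, and its median of -0.015 (percentile 56.8) changed sign when cells were weighted equally. Glucocorticoid response genes had a median of -0.33 (percentile 1.85), and immediate early genes a median of -0.24 (percentile 2.27), with Jun at log2 -0.58 and Jund at -0.24. All 12 measured mitochondrially encoded genes were above 0 (median 0.52, percentile 99.99). The neutrophil genes S100a8 and S100a9 had 559 and 321 UMIs against 1 each, and were 425 and 244 CPM in the treatment-MI library. In that library S100a8 was 0.871 CPM in microglia-like and 0.874 CPM in astrocyte-like cells, and S100a9 was 1.37 and 1.41 CPM. The source of these UMIs in the macrophage class was not tested.

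The highest single genes in this class included Elane, Prtn3, H2-M2, Fabp4, Ccl2, Ccl7, Ccl12, Cebpb and Wdr89. All 399 Elane UMIs and 99.5% of the 442 Prtn3 UMIs in the treatment-MI library came from 1 cell, so that the ratios of these granule protease genes describe that cell. H2-M2 and Fabp4 had 0 UMIs in the treatment-sham library, at least 8.79-fold and 8.39-fold higher in the treatment-MI library against the limit of 3 counts over the class, with UMIs in 6 cells each. The 10 lowest were Tnip3, Gpr132, Cxcl9, Klrb1b, Nans, Fgf13, Snhg1, Creb5, Fes and Fxyd5, with log2 ratios from -1.62 to -0.82. Cxcl9 had UMIs in 4 and 2 cells only, and Tnip3, at log2 -1.54 in the class, was at -0.48 in its macrophage sub-clusters alone.

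Many genes differed alike in unrelated classes. Across the 4266 genes measured in both microglia-like and astrocyte-like cells at levels that free RNA could not supply, the log2 ratios of both classes correlated with Pearson r of 0.81 and Spearman rho of 0.77. This correlation is across genes, which are not independent replicates, and no p-value is given. Cebpb, Pfn1, Snhg8, Snrpf, Cox17, Smim26 and B2m were among 38 genes at least 2-fold higher in the treatment-MI library in both classes, a set chosen after seeing the data. Only 13 of the 38 lay, in both classes, above the level that free RNA from other classes could supply. In each of 6 other classes, those of the 38 that were measured (20 to 36 genes) had a median log2 ratio above 0. Free RNA differed as well: Gh, which brain cells hardly make, was 1438 CPM in microglia-like and 1239 CPM in astrocyte-like cells of the treatment-MI library and 0.0737 and 0.140 CPM in the treatment-sham library. The haemoglobin gene Hbb-bs was 285 CPM against 16.96 CPM in microglia-like cells and 388 CPM against 12.3 CPM in astrocyte-like cells. Ttr, from the choroid plexus, was 74.5 CPM against 66.8 CPM in microglia-like cells.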

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

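The tests of free hormone RNA, of pituitary tissue, of transcript length, of the genes shared between classes and of a response to the surgery were chosen after the result was seen, and the set of shared genes was redefined after its first version had fixed the outcome of the test of free RNA. Apart from the cells used in the comparisons, the treatment-MI library held 619 cells in clusters led by pituitary hormone genes against 5 in the other library, 199 cells in the unnamed cluster led by platelet genes against 13, and, among barcodes left out by the cell filter, 657 with over 50% of their UMIs from haemoglobin genes or Alas2 against 27. The treatment-sham library held 17 olfactory ensheathing cell-like cells against 0 in the treatment-MI library.

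For the hormone-gene cells, free hormone RNA in the droplets of cells of the named classes is argued against. Such droplets would hold the marker genes of those cells, but the median marker level, per UMI outside the 7 hormone genes and as a percentage of the level in the own class, came to 4.27% summed over the named classes, with microglia-like cells highest at 1.27%. A UMI of Pitx1 or Pou1f1, transcription factors of the pituitary, was present in 95.6% of their cells in the treatment-MI library against 0.892% of astrocyte-like cells, which fits pituitary tissue collected with the brain in the treatment-MI pool. Hormone genes switched on in brain neurons remained open, since 39.6% had a UMI of Rbfox3, Slc17a6, Slc17a7, Gad1 or Gad2, between the bounds set beforehand. This share and that of Pitx1 or Pou1f1 were counted without thinning. The hormone-gene cells had a median of 25433 UMIs against 7850 in astrocyte-like cells, so depth enters both shares. A candidate explanation is therefore that dissection differed between the pools, which would alter cell shares without any effect of the surgery. The log2 share ratio of the hormone-gene clusters was 6.72 with doublet calls left out. With doublet calls kept it was 7.69, where the treatment-sham library held 0 such cells and was set at the limit of 3. It was 3.20 without a cell filter and 3.22 at resolution 0.5, where a cluster led by neuroblast genes was counted with them.

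The 38 genes at least 2-fold higher in both microglia-like and astrocyte-like cells had a median annotated transcript length of 770 bases, against 2077.5 for all genes measured in microglia-like cells, and a median log2 ratio of 1.38. Other genes of matched annotated length had a median of -0.024 (random sets of such genes -0.14 to 0.07), which argues against a bias with annotated length as the whole cause. Copies of other genes may account for part: 21.1% of the 38 have 50% or more of the 31-base words of their 3′ end in another gene, against 2.93% of genes matched on expression. Free RNA may account for another part, since 28.9% (11 genes, among them Gh, Prl, Pomc and 4 haemoglobin genes) were at least 5 times higher in the hormone-gene, erythroid-like or unnamed clusters, and the other 27 had a median log2 ratio of 1.27, although only 13 of the 38 lay above the level that free RNA of any other class could supply in both classes. The median of the measured shared genes was above 0 in all 6 other classes examined, as a response of all cell types or a difference in handling or library preparation would give, although the 4 haemoglobin genes were below 0 in neuroblast-like cells. With 1 library per group these cannot be told apart.

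For the MHC class I genes, with a median of 0.52 in microglia-like cells, other genes of matched annotated transcript length had a median of 0.0261 (random sets of such genes -0.19 to 0.27). The list lay at percentile 100 among random lists matched on expression and annotated length, which argues against a bias with annotated length as the whole cause. As part of the difference it remained open, since the upper end of the random sets reaches 50% of the median of the list. Shared reads between paralogs remained open: the 6 members with under 10% of their 3′ end words in another gene had a median of 0.21, between the bounds set beforehand, although B2m with 0% shared stood at log2 1.16. The list was above 0 in all 3 compared classes, but B2m is also among the 38 shared genes. A response to the surgery and a difference between libraries cannot be told apart with 1 library per group.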

How the results depend on the processing

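The denominator without the hormone-gene, erythroid-like and unnamed low-UMI clusters and the macrophage sub-clusters alone were added after seeing the data. No paired analysis was possible because each group is 1 library. Of 36 alternative values for log2 share ratios, 28 stayed within the counting interval, as did 398 of 463 for list medians, 454 of 470 for named genes (none of the 470 with a change of sign) and 13 of 14 for shares of cells with a UMI. Shares: microglia-like, main -0.15, was -0.33 without a cell filter and 0.0225, with the opposite sign, on the denominator without those clusters. Astrocyte-like, main -0.27, was -0.12 without a cell filter, -0.51 with the strict filter, -0.40 outside microglia-like cells and -0.0912 without those clusters. The hormone-gene clusters, main 6.72, were at 3.20 without a cell filter and 3.22 at resolution 0.5, where a cluster with leading genes of neuroblasts and a hormone gene (84 and 62 cells, 113 and 62 cells) was counted with them. T cell-like cells stayed between 0.59 and 1.05. The share of macrophages with a Ccr2 UMI, main -0.53, was 0.23 when thinned to 500 UMIs, within its interval. Lists: disease-associated microglia in microglia-like cells, main -0.22, was -0.16 after median-ratio scaling, -0.31 at 200 UMIs and 50 CPM, and 0.23, with the opposite sign, at 10 UMIs without a minimum CPM. In astrocyte-like cells it was -0.31 with doublets kept and -0.0557 at 10 UMIs. NF-kB and cytokines in microglia-like cells, main 0.22, was 0.16 without a cell filter, 0.17 at resolution 0.5, 0.16 with each library clustered alone, 0.61 at 10 UMIs and 0.17 at 200 UMIs. MHC class I was 0.38 in astrocyte-like cells at 10 UMIs and 0.94 in macrophages at 200 UMIs, and the interferon list was 0.88 in the macrophage sub-clusters alone. The minimum counts change which members are measured; for the other changes the cause was not tested. Border-associated macrophages had no value with each library clustered alone, and erythroid-like cells none there or at resolution 0.5. MHC class I in astrocyte-like cells had too few members in 5 settings. The macrophage results rest on 159 and 110 cells.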

Other observations

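Classes with 50 to 99 cells in 1 or both libraries were examined after seeing the data, and so were all tests in this part. In oligodendrocyte-like cells (85 and 80 cells) the 16 myelin genes had a median log2 ratio of -0.09 (percentile 17.2 among random lists), with 11 below 0, among them Mal at -0.29 and Mbp at -0.13. Cholesterol synthesis genes, needed for myelin lipids, had a median of -0.30 (percentile 1.70, 6 of 9 below 0). All 7 measured immediate early genes were below 0, with a median of -0.65, among them Egr1 at log2 -1.60 and Jund at -0.35. In the same cells 12 of 13 mitochondrially encoded genes were above 0 (median 0.38, percentile 99.99), and so were all 4 measured genes of the homeostatic microglia list (median 3.07, percentile 100), which are genes of another class. In pericyte-like cells Spp1, the gene of osteopontin, was 448 CPM against 65.1 CPM, with UMIs in 24 of 78 and 4 of 51 cells and 66.9% of the treatment-MI UMIs in 5 cells. In endothelial-like cells the MHC class I list had a median of 1.11, with 8 of 8 members above 0.

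Endothelial-like cells of the treatment-MI library held 653 UMIs of Plvap, a protein of fenestrated capillaries, in 12 of 70 cells (17.1%, 9.18% to 28.0%), against 4 UMIs in 1 of 53 cells (1.89%, 0.0478% to 10.1%). Meis2 had 920 UMIs in 11 cells and 0 UMIs in the treatment-sham library. The blood-brain barrier list, which includes Cldn5 and Slco1a4, had a median of -0.40 (percentile 0.19) over all endothelial-like cells and -0.0027 (percentile 49.5) without the cells that had a Plvap UMI, and MHC class I was then at 0.48. The lower barrier genes in the treatment-MI library thus rested on these few cells.

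In neuroblast-like cells all 312 Cd74 UMIs of the treatment-MI library lay in 1 cell, and in oligodendrocyte-like cells 58.1% of the 62 P2ry12 UMIs lay in 1 cell.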
